A study of Mus musculus with 9 samples.

How the data were processed

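RNA was measured in 9 libraries of labial mucosa from mice of 3 strains, with 3 libraries each, prepared with a stranded kit for polyadenylated RNA per the labels' protocols. The deposited values are expected counts per gene (estimated counts that need not be whole), in files that give a gene symbol and a count, per the file headers. Per the submitters' processing notes, STAR, RSEM and GRCm38 were used. Versions, the annotation and the strand setting are not given in the sources used here, so a gene and its antisense partner, overlapping genes and near-identical copies may share reads. Each library held 2710 to 3195 values that were not whole.

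Each file held 55450 lines, of which 107 symbols stood on several and were summed, leaving 55342 names. Another 27 names looked like dates and were kept as given. Coordinates came from a GENCODE annotation of GRCm38 matched by symbol. Expected counts were rounded to whole numbers before any test. Total expected counts ran from 27192359 to 46456500. Replicates of a strain differed by more than sampling noise, with a chi-square per degree of freedom of 15.7 to 95.4. This sets their spread against counting noise only, so it cannot tell separate animals from repeat libraries of a sample. Each library was used as its own replicate.

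Strains and replicate numbers were taken from the labels, and all pairs of strains and the 3 strains together were compared. EdgeR 4.0.16 (quasi-likelihood test, TMM factors, its own expression filter) in R 4.3.3 was fitted to all 9 libraries with 1 mean per strain and 6 residual degrees of freedom, which left 16523 genes tested. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The SE is the size of the log2 fold change divided by the square root of the F statistic and is approximate. CPM use the library sizes scaled by the TMM factors. Limits for genes at 0 take 3 counts over the group, and 95% counting intervals are exact, and both cover counting error only.

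Lists of genes for cell types, pathways and tissues were written before the data were examined, together with the tests, the alternatives and the rule for naming genes. The rule took Rag1, Rag2, Il2rg and Nnt in every library. Per comparison it added the 10 highest and 10 lowest fold changes among called genes with a mean of 5 CPM or more in the higher strain and no overlap between the libraries of the strains, leaving out predicted genes, mitochondrial genes, pseudogenes and antigen receptor segments. It also took up to 4 members of each list with the smallest adjusted p. The 28 lists with 3 or more tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. For each list, members were also adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

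The alternatives were median-ratio and upper-quartile factors, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM or more in 3 libraries, a replicate block, only the 6 libraries of a comparison, each library left out in turn, an estimated correlation and fry for lists, and windows of 5 and 20 Mb for the position of called genes. Added after seeing the data were limma on log2(CPM + 1) and robust dispersions. Ranges given as alternatives are the lowest and highest adjusted p over the alternatives for that result. The tests were first checked on simulated counts with 200 changed genes. Each gene was drawn on its own with the dispersion fitted to these data. The false calls given for each comparison therefore leave out variation that genes share, as from differing tissue content. The median log2 fold change of all genes stayed within 0.1 of 0 under every scaling.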

Results

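Bulk sequencing of polyadenylated RNA was carried out on labial mucosa biopsies of mice of 3 strains, labelled B6, Tac111 and Tac146, with 3 libraries per strain. Per the protocol given with each library, mice were infected before biopsy. The agent, and whether dose and time were alike in the 3 strains, are not given in the sources used here. The labels name the cells of the B6 libraries as type 1 innate lymphoid cells (ILC1), and those of the Tac111 and Tac146 libraries as T cells, so strain and labelled cell type changed together in both comparisons with B6. Total expected counts were 40873064, 28065745 and 31240102 in B6 replicates 1, 2 and 3. The Tac111 replicates 1, 2 and 3 held 30609090, 27192359 and 35955305, and Tac146 replicates 2, 3 and 4 held 43916317, 33085143 and 46456500. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these samples, which may be technical. Levels are given as CPM, counts scaled to a common library size, as mean ± SD over the 3 libraries of a strain (n = 3), and fold changes are on the log2 scale with their standard error (SE).

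Transcripts of squamous epithelium and skeletal muscle were abundant in all 9 libraries. Krt4 and Krt13, the keratin pair of the upper layers of oral epithelium, together took 5.28 to 8.87% of the counts. The skeletal muscle list took 2.86 to 5.55%, with the lowest value in Tac146 replicate 4 and 4.37% or more in the other libraries. By contrast, the T cell markers took 0.0049 to 0.0080% and the ILC1 and natural killer (NK) cell markers 0.0012 to 0.0058%. Ptprc, which encodes the leukocyte surface protein CD45, took 0.00043 to 0.00129%. Mitochondrial transcripts took 5.38 to 6.02% of the counts in B6, 6.08 to 7.50% in Tac111 and 5.22 to 6.10% in Tac146. The first principal component (42.3% of the variance) placed the Tac111 libraries at 38.8 to 47.1 and the other libraries at -30.8 to -8.38. On the second component (16% of the variance), Tac146 replicate 4 stood at -43.9, and the other 8 libraries lay between -11.5 and 20.5.

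Il2rg, Rag1, Rag2 and Nnt each separated 1 strain from the others. Il2rg (chromosome X, 101264378 to 101268255, GRCm38) encodes the receptor chain shared by interleukins 2, 4, 7, 9, 15 and 21, and stood at 5.04 ± 0.201 CPM in B6, 0.118 ± 0.010 in Tac111 and 4.35 ± 0.891 in Tac146. It fell in Tac111 against B6 (log2 fold change -5.38, SE 0.26, edgeR adjusted p = 3.59e-06). It had 216, 148 and 145 counts in the B6 libraries and 4, 3 and 4 in the Tac111 libraries. Rag1 (chromosome 2, 101638282 to 101649501), a component of the recombinase that assembles antigen receptor genes, had 71, 59 and 75 counts in the Tac146 libraries. The B6 libraries together had 3 and the Tac111 libraries together 4. Its level in Tac146 was 1.68 ± 0.123 CPM, a ratio to B6 of 56.0 (95% counting interval 18.9 to 274, edgeR adjusted p = 0.00210). Rag2 (chromosome 2, 101624718 to 101632529), the partner of Rag1, had 51, 47 and 75 counts in the Tac111 libraries and 0 in the others. It was at least 62.3-fold higher in Tac111 than in B6 (edgeR adjusted p = 0.00124) and at least 76.1-fold higher than in Tac146 (edgeR adjusted p = 0.000810), taking 3 counts over the group as the floor. Nnt, which encodes a mitochondrial proton-pumping transhydrogenase, stood at 96.1 ± 4.07 CPM in B6, 99.5 ± 2.55 in Tac111 and 26.9 ± 5.07 in Tac146. It fell in Tac146 against B6 (log2 fold change -1.84, SE 0.13, edgeR adjusted p = 8.30e-05). Sequence around these genes was not analysed here, so the counts do not say which part of a transcript they come from.

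**Figure D1:**
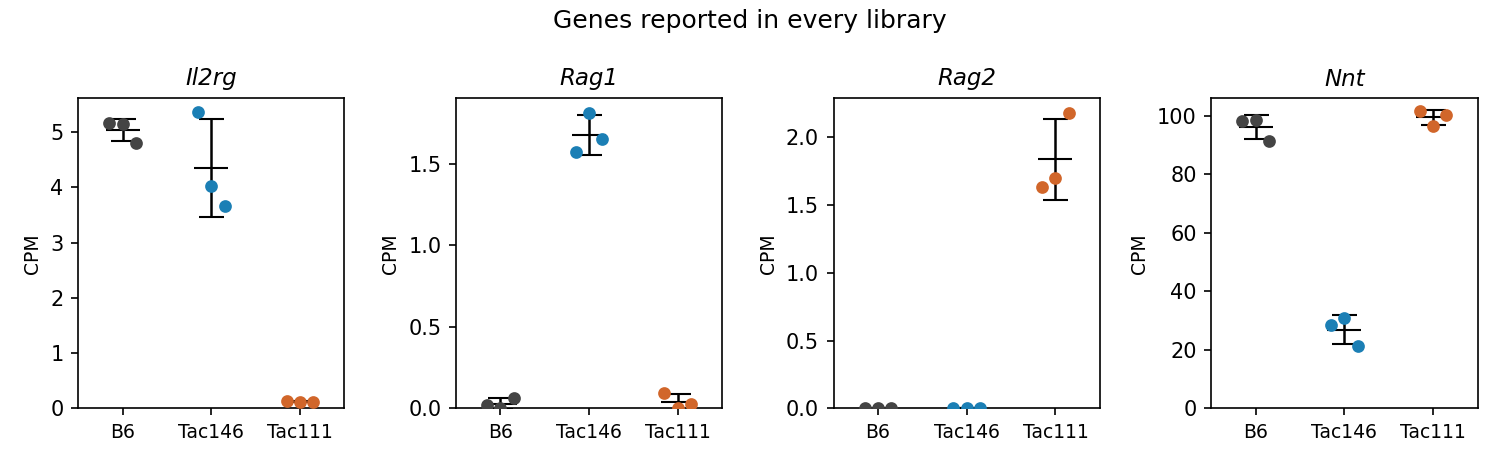
CPM per library (points) with the strain mean and SD (bars, n = 3) for Il2rg, Rag1, Rag2 and Nnt, with strains on the x axis. The Tac111 libraries sat lowest for Il2rg and alone held Rag2 counts, and the Tac146 libraries sat highest for Rag1 and lowest for Nnt.

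The comparison of Tac111 with B6 asked how transcription in the mucosa differed between these strains. Lymphocyte transcripts fell in Tac111. Gzmc, which encodes a granzyme of cytotoxic lymphocytes, stood at 5.34 ± 1.35 CPM in B6 and had 0 counts in the Tac111 libraries, at least 163-fold lower (edgeR adjusted p = 7.24e-05). Itgae, an integrin chain of lymphocytes resident in epithelium, fell from 4.78 ± 0.783 to 0.210 ± 0.143 CPM (log2 fold change -4.46, SE 0.35, edgeR adjusted p = 0.000107), and Il2rb, a receptor chain for interleukins 2 and 15, was 58.0-fold lower (log2 fold change -5.86, SE 0.52, edgeR adjusted p = 0.000276). Of 21 tested ILC1 and NK cell markers, 18 fell (18 adjusted over the list alone), with a median log2 fold change of -3.49 (camera, adjusted p = 1.05e-53), or -3.21 with genes at 0 set to their bound. Of 22 T cell markers, 11 fell (17 adjusted over the list alone), with a median log2 fold change of -2.00 (camera, adjusted p = 8.94e-25). Among them, Cd3e and Cd3g, which encode chains of the T cell receptor complex, had 0 counts in Tac111 and were at least 41.6-fold and 71.2-fold lower (edgeR adjusted p = 0.000728 and 0.000500). Of 4 tested gamma delta T cell markers, 3 fell (3 adjusted over the list alone), with a median log2 fold change of -5.91 (camera, adjusted p = 5.59e-09), or -4.32 with genes at 0 set to their bound. Trdc, the constant region of the delta receptor chain, was 20.4-fold lower (log2 fold change -4.35, SE 0.47, edgeR adjusted p = 0.000790). These 3 lists also passed with an estimated correlation (camera, adjusted p = 0.00200, 0.00200 and 0.00806).

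Other lymphoid lists were also lower in Tac111 than in B6, with a smaller share of their tested members called. Of 12 ILC2 and ILC3 markers, Il7r, Rora and Ltb fell (3 adjusted over the list alone), with a median log2 fold change of -0.24 (camera, adjusted p = 0.00620), adjusted p = 0.0643 with an estimated correlation, alternatives 4.89e-06 to 0.0643. Of 16 gamma chain cytokine and receptor genes, 4 fell (6 adjusted over the list alone), with a median log2 fold change of -0.31 (camera, adjusted p = 7.02e-07), which also passed with an estimated correlation (adjusted p = 0.0474). Il7r, the receptor chain for interleukin 7, was 6.09-fold lower (log2 fold change -2.61, SE 0.30, edgeR adjusted p = 0.00112). The 7 tested B and plasma cell markers had a median log2 fold change of -1.05 (camera, adjusted p = 0.0119), adjusted p = 0.181 with an estimated correlation, alternatives 0.00255 to 0.181, and adjusted p = 0.0519 without Tac111 replicate 1. Of these, 4 fell adjusted over the list alone and edgeR called 0 over all genes, with 4 at an unadjusted p under 0.05 and 0 by DESeq2.

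Genes that respond to interferon and genes of antigen presentation fell in Tac111 against B6. Cxcl10, a chemokine that attracts activated lymphocytes, went from 3.43 ± 1.47 to 0.181 ± 0.104 CPM (log2 fold change -4.20, SE 0.47, edgeR adjusted p = 0.000926). Nlrc5, a transactivator of MHC class I genes, was 4.23-fold lower (log2 fold change -2.08, SE 0.17, edgeR adjusted p = 0.000150), and B2m, the light chain of MHC class I, fell from 333 ± 31.8 to 116 ± 10.5 CPM (log2 fold change -1.53, SE 0.10, edgeR adjusted p = 2.90e-05). Of 32 interferon gamma response genes, 27 fell (30 adjusted over the list alone), with a median log2 fold change of -1.41 (camera, adjusted p = 8.23e-52), and the list also passed with an estimated correlation (adjusted p = 0.0270). Of 43 type I interferon response genes, 28 fell (39 adjusted over the list alone), with a median log2 fold change of -1.39 (camera, adjusted p = 1.32e-41), adjusted p = 0.0700 with an estimated correlation, alternatives 2.25e-88 to 0.0700. Rsad2, which encodes the antiviral enzyme viperin, was 7.02-fold lower (log2 fold change -2.81, SE 0.32, edgeR adjusted p = 0.00109). Of 14 MHC class I presentation genes, 7 fell (11 adjusted over the list alone), with a median log2 fold change of -0.75 (camera, adjusted p = 9.76e-29). Of 12 MHC class II presentation genes, 8 fell (11 adjusted over the list alone), with a median log2 fold change of -1.01 (camera, adjusted p = 9.51e-15). Both MHC lists passed with an estimated correlation (adjusted p = 0.00825 and 0.0351). H2-Aa, a class II chain, fell by 1.03 on the log2 scale (SE 0.15, edgeR adjusted p = 0.00359). Reads of H2-Q6 and H2-Q7, and of the Gbp and Oas1 copies, can be shared between near-identical genes, and their single values are uncertain.

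**Figure D2:**
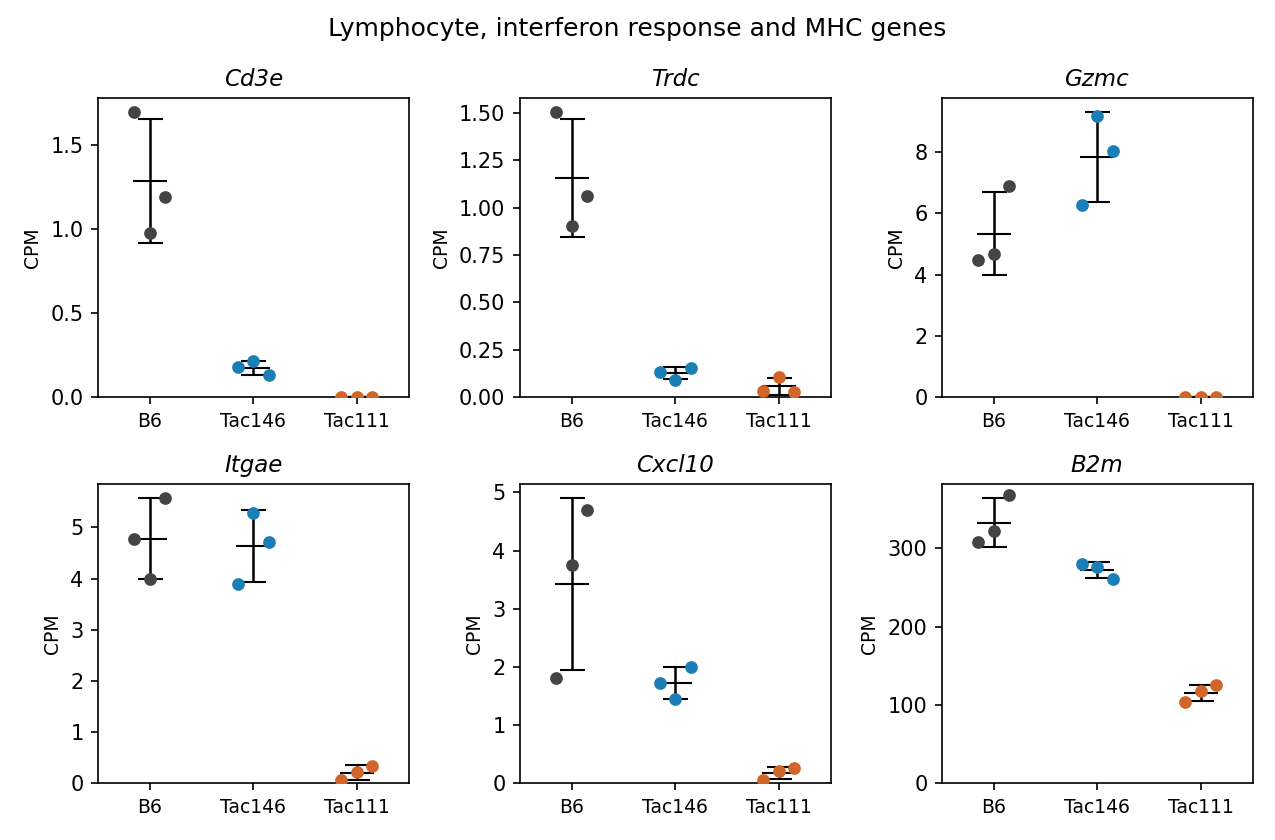
CPM per library (points) with the strain mean and SD (bars, n = 3) for 6 lymphocyte, interferon response and MHC genes, with strains on the x axis. Tac111 had the lowest mean in each panel, and Tac146 lay near B6 for Itgae and below it for Cd3e and Trdc.

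Chil4, Sprr2a2 and Alox15 dropped to low levels in Tac111. Chil4, a chitinase-like protein gene (chromosome 3, 106201490 to 106219507), fell from 1802 ± 553 to 0.675 ± 0.494 CPM (log2 fold change -11.41, SE 0.61, edgeR adjusted p = 6.89e-06). Sprr2a2 (chromosome 3, 92215920 to 92256724), 1 of the small proline-rich proteins of the cornified envelope, fell from 1793 ± 451 to 5.61 ± 0.690 CPM (log2 fold change -8.32, SE 0.37, edgeR adjusted p = 3.59e-06). Alox15, a lipoxygenase gene (chromosome 11, 70344152 to 70352031), fell from 208 ± 96.1 to 4.02 ± 0.737 CPM (log2 fold change -5.69, SE 0.37, edgeR adjusted p = 2.89e-05). Sprr2a1 overlaps Sprr2a2 in the annotation, and near-identical copies (Sprr2a1, Sprr2a2 and Sprr2a3, and likewise Chil3 and Chil4) can share reads, so the split among them is uncertain. Of 35 differentiated keratinocyte genes, only Sprr2a1, Sprr2a2 and Sprr2a3 fell by edgeR (3 adjusted over the list alone). That list had a median log2 fold change of 0.00 and a mean of -0.68, and its test was lower (camera, adjusted p = 1.88e-05, adjusted p = 0.245 with an estimated correlation, alternatives 7.52e-09 to 0.245). Aqp5, a water channel gene of glands, rose from 5.48 ± 1.89 to 21.1 ± 5.76 CPM (log2 fold change 1.96, SE 0.31, edgeR adjusted p = 0.00697). Raver2, which encodes an RNA-binding protein, rose as well (log2 fold change 1.84, SE 0.25, edgeR adjusted p = 0.00261).

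Among tissue lists, endothelial genes fell in Tac111 against B6. Of 18 endothelial and lymphatic genes, 7 fell (11 adjusted over the list alone), with a median log2 fold change of -0.54 (camera, adjusted p = 3.98e-13), adjusted p = 0.0707 with an estimated correlation, alternatives 2.42e-18 to 0.0707. Cdh5, the cadherin of endothelial junctions, fell from 34.1 ± 4.14 to 14.8 ± 1.86 CPM (log2 fold change -1.21, SE 0.13, edgeR adjusted p = 0.000728). Of 22 macrophage and dendritic cell markers, Itgax and Cd207 fell (4 adjusted over the list alone), with a median log2 fold change of -0.51 (camera, adjusted p = 3.93e-07), adjusted p = 0.222 with an estimated correlation, alternatives 1.64e-10 to 0.222. Cd207, the langerin gene of Langerhans cells, was 3.85-fold lower (log2 fold change -1.94, SE 0.23, edgeR adjusted p = 0.00124). Of 23 immediate early and stress genes, 3 fell (7 adjusted over the list alone), with a median log2 fold change of -0.18 (camera, adjusted p = 2.87e-06), and the list passed with an estimated correlation (adjusted p = 0.0477). The hair follicle and sebaceous gland list was the only list called higher, with a median log2 fold change of 0.80 (camera, adjusted p = 2.87e-06), adjusted p = 0.357 with an estimated correlation, alternatives 1.36e-16 to 0.357. EdgeR called 0 of its 26 members, with 9 at an unadjusted p under 0.05 and 1 by DESeq2, and 0 were called adjusted over the list alone. The basal keratinocyte list was lower, with a median log2 fold change of -0.19 (camera, adjusted p = 0.0272), adjusted p = 0.325 with an estimated correlation, alternatives 0.00367 to 0.325, and adjusted p = 0.0633 without B6 replicate 3 and 0.0548 without Tac111 replicate 2. EdgeR called 0 of its 17 members (1 lower adjusted over the list alone), with 6 at an unadjusted p under 0.05 and 3 by DESeq2. Of 15 adipocyte genes, 1 fell (1 adjusted over the list alone), with a median log2 fold change of -0.50 (camera, adjusted p = 0.00885), adjusted p = 0.428 with an estimated correlation, alternatives 2.00e-05 to 0.428, and adjusted p = 0.114 without B6 replicate 1 and 0.0565 without Tac111 replicate 2.

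Camera did not call 11 lists between Tac111 and B6. Median log2 fold changes were -0.35 (adjusted p = 0.0832) for neutrophil markers, 0.12 (adjusted p = 0.377) for mast cell markers and -0.22 (adjusted p = 0.0530) for epithelial antimicrobial and interleukin 17 response genes. They were -0.18 (adjusted p = 0.0822) for wound keratinocyte genes, -0.05 (adjusted p = 0.534) for fibroblast and matrix genes, 0.04 (adjusted p = 0.994) for skeletal muscle and 0.21 (adjusted p = 0.588) for salivary and mucous gland genes by camera. Melanocyte and Schwann cell genes had -0.21 (adjusted p = 0.701) with a mean of 0.27, erythroid genes -0.37 (adjusted p = 0.263), proliferation genes 0.18 (adjusted p = 0.0530) and mitochondrial transcripts 0.20 (adjusted p = 0.0804) by camera. Within these lists edgeR still called 1 lower of 10 neutrophil (1 lower adjusted over the list alone), 2 lower of 15 antimicrobial (4 lower adjusted over the list alone), 1 lower of 23 fibroblast (1 lower adjusted over the list alone), 1 higher of 9 salivary and mucous gland (1 higher and 2 lower adjusted over the list alone) and 1 higher and 2 lower of 15 melanocyte and Schwann cell (3 higher and 4 lower adjusted over the list alone) genes. Some of these lists passed the threshold when single libraries were left out, also libraries of Tac146, which this comparison does not contrast. By camera, neutrophil markers had adjusted p = 0.0260 without B6 replicate 2 and 0.0317 without Tac111 replicate 3, alternatives 0.0224 to 0.285. Antimicrobial genes had camera adjusted p = 0.00964 without B6 replicate 2, 0.00189 without Tac111 replicate 3, 0.0145 without Tac146 replicate 2, 0.0456 without Tac146 replicate 3 and 0.0391 without Tac146 replicate 4, alternatives 0.00189 to 0.357. Wound keratinocyte genes had camera adjusted p = 0.0246 without B6 replicate 2, 0.0368 without Tac111 replicate 3 and 0.0367 without Tac146 replicate 4, alternatives 0.0199 to 0.324. For erythroid genes camera gave adjusted p = 0.0297 without B6 replicate 3, alternatives 0.0297 to 0.673. For proliferation genes camera gave adjusted p = 0.0438 without B6 replicate 2, 0.00253 without Tac111 replicate 3, 0.0319 without Tac146 replicate 2, 0.0456 without Tac146 replicate 3 and 0.0129 without Tac146 replicate 4, alternatives 0.00253 to 0.460. For mitochondrial transcripts camera gave adjusted p = 0.0451 without B6 replicate 2, 0.0264 without Tac111 replicate 2 and 0.0368 without Tac111 replicate 3, alternatives 0.0264 to 0.456.

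Over all 16523 genes tested, edgeR called 630 between Tac111 and B6, of which 168 were higher and 462 lower in Tac111. Of these, 304 differed by over 2-fold, 41 higher and 263 lower. In 29.6% of the genes tested all 3 libraries of 1 strain lay above all 3 of the other, against 10% by chance. The count fell without each of the 6 compared libraries. It was 462, 349 and 320 without B6 replicates 1, 2 and 3, of which 83, 75 and 56 were higher. It was 472, 295 and 359 without Tac111 replicates 1, 2 and 3, of which 106, 58 and 78 were higher. Without Tac146 replicate 4 it was 958. Leaving out a library also lowers the power of the test, so these falls do not single out a library. With only the 6 libraries of these strains the split was 311 higher and 571 lower. The count was 1161 with DESeq2 and 1020 with no filter on low counts. In simulated counts with 200 changed genes for this comparison, edgeR recovered 16.4% of 1.5-fold, 64.2% of 2-fold and 84.8% of 4-fold changes, with 4 false calls. DESeq2 made 18 false calls in the same counts.

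The comparison of Tac146 with B6 asked the same question for the other Tac strain. T cell receptor complex genes were lower in Tac146, while the ILC1 and NK cell list was not called. Of 22 T cell markers, Cd3d, Cd3e, Cd3g and Trac fell (10 adjusted over the list alone), with a median log2 fold change of -0.86 (camera, adjusted p = 3.09e-24), which also passed with an estimated correlation (adjusted p = 0.00448). Cd3e went from 1.29 ± 0.370 to 0.175 ± 0.0414 CPM (log2 fold change -2.89, SE 0.37, edgeR adjusted p = 0.0161), and Cd3d had 83 counts in the B6 libraries and 3 in the Tac146 libraries, a ratio of 33.8 (95% counting interval 11.2 to 167, edgeR adjusted p = 0.0125). Of 4 gamma delta T cell markers, Trdc fell (2 adjusted over the list alone), with a median log2 fold change of -1.90 (camera, adjusted p = 2.55e-09), which also passed with an estimated correlation (adjusted p = 0.0102). Trdc went from 1.16 ± 0.311 to 0.126 ± 0.0316 CPM (log2 fold change -3.14, SE 0.38, edgeR adjusted p = 0.00651). The 21 ILC1 and NK cell markers had a median log2 fold change of 0.05 (camera, adjusted p = 0.642). EdgeR called 0 of them, with 1 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 were called adjusted over the list alone. In edgeR, Cd3d had adjusted p = 0.0529 without B6 replicate 2, 0.0537 without B6 replicate 3 and 0.0752 without Tac146 replicate 3 (alternatives 0.000264 to 0.130). Cd3e had edgeR adjusted p = 0.0538 without B6 replicate 1, 0.0619 without B6 replicate 3, 0.0736 without Tac146 replicate 2, 0.0737 without Tac146 replicate 3 and 0.0674 without Tac146 replicate 4 (alternatives 2.97e-05 to 0.181). Cd3g had edgeR adjusted p = 0.0405 with all libraries, and 0.124 without B6 replicate 1, 0.154 without B6 replicate 2, 0.153 without B6 replicate 3, 0.0520 without Tac111 replicate 3, 0.182 without Tac146 replicate 3 and 0.0581 without Tac146 replicate 4 (alternatives 1.54e-05 to 0.210). Trac had edgeR adjusted p = 0.0434 with all libraries, and 0.0666 to 0.182 without each of the 9 libraries in turn (alternatives 0.0253 to 0.182).

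Chil1, Serpinb3c, Lpo and Sprr2f were among the genes that rose in Tac146 against B6. Chil1, a chitinase-like protein gene, went from 9.47 ± 5.11 to 101 ± 27.5 CPM (log2 fold change 3.40, SE 0.39, edgeR adjusted p = 0.00518). Serpinb3c, a serine protease inhibitor gene, was 10.5-fold higher (log2 fold change 3.40, SE 0.37, edgeR adjusted p = 0.00418), and Lpo, which encodes the lactoperoxidase of glandular secretions, rose from 0.565 ± 0.374 to 6.77 ± 1.70 CPM (log2 fold change 3.51, SE 0.40, edgeR adjusted p = 0.00467). Sprr2f was 14.5-fold higher (log2 fold change 3.86, SE 0.44, edgeR adjusted p = 0.00467). Of 9 salivary and mucous gland genes, Lpo rose (3 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.79 (camera, adjusted p = 0.000256), adjusted p = 0.165 with an estimated correlation, alternatives 4.70e-06 to 0.165. Of 35 differentiated keratinocyte genes, Sprr2a1, Sprr2a2 and Sprr2a3 rose (3 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.12 (camera, adjusted p = 1.81e-05), adjusted p = 0.299 with an estimated correlation, alternatives 2.43e-07 to 0.299. Sprr2a2 was 4.34-fold higher (edgeR adjusted p = 0.00913), with the same uncertainty from shared reads, and had edgeR adjusted p = 0.0804 with only the 6 libraries compared (alternatives 4.17e-14 to 0.0804). Sprr2a1 had edgeR adjusted p = 0.00642 with all libraries, and 0.0512 with only the 6 libraries compared (alternatives 2.97e-11 to 0.0512). Chil4 and Alox15 did not pass (edgeR adjusted p = 0.105 and 0.455, alternatives 0.000213 to 0.489 and 0.0332 to 0.910). Sprr2a3 had edgeR adjusted p = 0.0174 with all libraries, and 0.0510 without B6 replicate 1, 0.128 without B6 replicate 2 and 0.0594 without B6 replicate 3 (alternatives 6.04e-06 to 0.128). Of 15 antimicrobial and interleukin 17 response genes, Saa1, an acute-phase protein gene, and Nfkbiz, a regulator of nuclear factor kappa B target genes, rose (5 adjusted over the list alone), with a median log2 fold change of 0.39 (camera, adjusted p = 5.64e-09), adjusted p = 0.0679 with an estimated correlation, alternatives 6.88e-11 to 0.0679. Saa1 had edgeR adjusted p = 0.010 with all libraries, and 0.0619 without B6 replicate 3 (alternatives 1.30e-09 to 0.0649). Nfkbiz had edgeR adjusted p = 0.0389, and 0.243 without B6 replicate 2, 0.173 without B6 replicate 3, 0.0666 without Tac111 replicate 1, 0.0769 without Tac111 replicate 2, 0.0767 without Tac111 replicate 3, 0.181 without Tac146 replicate 3 and 0.0963 without Tac146 replicate 4 (alternatives 7.63e-05 to 0.243).

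**Figure D3:**
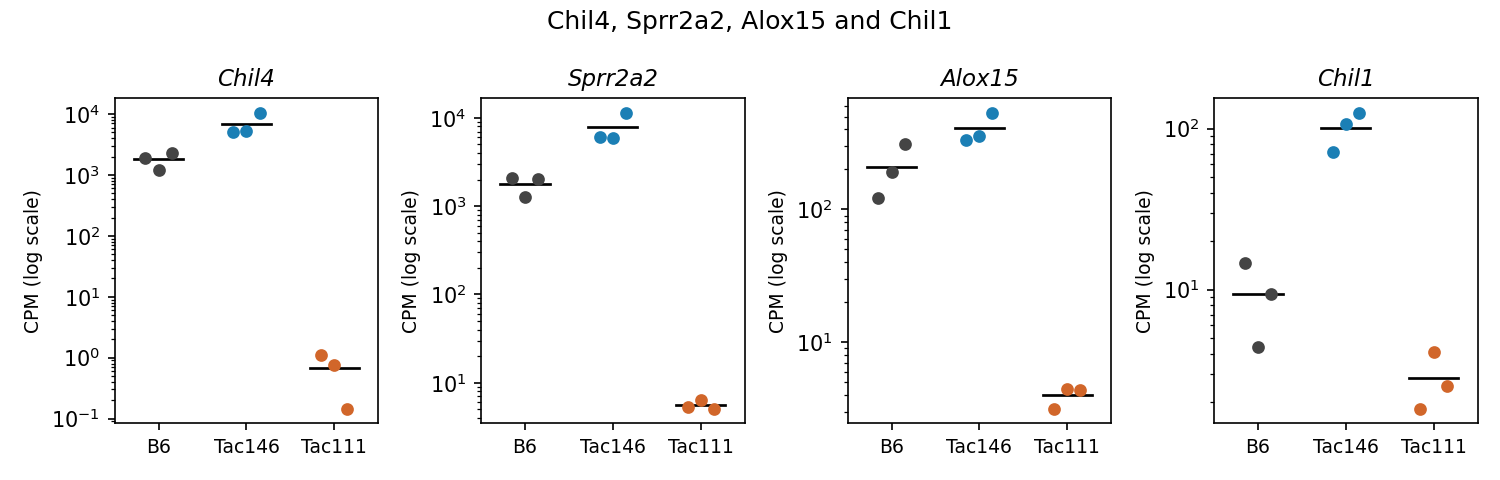
CPM per library (points, log scale) with the strain mean (line, n = 3) for Chil4, Sprr2a2, Alox15 and Chil1, with strains on the x axis. All Tac111 libraries lay below all B6 libraries in each panel, and all Tac146 libraries lay above them.

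Some of the genes lower in Tac146 than in B6 had a narrow spread between libraries. Wdfy1, which encodes an endosomal protein (chromosome 1, 79702262 to 79776143), fell from 27.2 ± 0.283 to 5.02 ± 0.312 CPM (log2 fold change -2.44, SE 0.09, edgeR adjusted p = 7.11e-07). Atp5e, a subunit of mitochondrial ATP synthase (chromosome 2, 174461072 to 174464105), fell from 222 ± 31.5 to 31.8 ± 3.06 CPM (log2 fold change -2.80, SE 0.16, edgeR adjusted p = 3.05e-05). Cd59a, an inhibitor of complement attack (chromosome 2, 104095801 to 104115354), fell from 36.4 ± 1.22 to 9.37 ± 1.26 CPM (log2 fold change -1.96, SE 0.11, edgeR adjusted p = 3.05e-05), and stood at 10.4 ± 0.964 CPM in Tac111 (log2 fold change -1.81, SE 0.11, edgeR adjusted p = 1.81e-05). Of 43 type I interferon response genes, Ifi27l2a fell (23 adjusted over the list alone), with a median log2 fold change of -0.77 (camera, adjusted p = 1.26e-28), adjusted p = 0.165 with an estimated correlation, alternatives 8.65e-96 to 0.165. The 32 interferon gamma response genes had a median log2 fold change of -0.35 (camera, adjusted p = 6.52e-13), adjusted p = 0.212 with an estimated correlation, alternatives 5.09e-42 to 0.212. Of these, 14 fell adjusted over the list alone and edgeR called 0 over all genes, with 14 at an unadjusted p under 0.05 and 4 by DESeq2.

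Further lists were called between Tac146 and B6. Of 19 wound keratinocyte genes, Sprr2d and Sprr2h rose (2 adjusted over the list alone), with a median log2 fold change of 0.17 (camera, adjusted p = 0.00801), adjusted p = 0.212 with an estimated correlation, alternatives 0.00142 to 0.212, and adjusted p = 0.122 without Tac146 replicate 4. In edgeR, Sprr2d had adjusted p = 0.0389, and 0.185 without B6 replicate 3, 0.0748 without Tac111 replicate 1, 0.0750 without Tac111 replicate 2, 0.0912 without Tac111 replicate 3, 0.0833 without Tac146 replicate 3 and 0.0510 without Tac146 replicate 4 (alternatives 7.40e-06 to 0.196). Sprr2h had edgeR adjusted p = 0.0458, and 0.128 without B6 replicate 2, 0.176 without B6 replicate 3, 0.0748 without Tac111 replicate 1, 0.102 without Tac111 replicate 2, 0.0818 without Tac111 replicate 3, 0.107 without Tac146 replicate 3 and 0.0790 without Tac146 replicate 4 (alternatives 3.68e-05 to 0.183). Neutrophil markers were higher, with a median log2 fold change of 0.38 (camera, adjusted p = 0.000718), adjusted p = 0.0679 with an estimated correlation, alternatives 2.70e-05 to 0.0679. MHC class II genes were higher, with a median log2 fold change of 0.18 (camera, adjusted p = 0.0466), adjusted p = 0.531 with an estimated correlation, alternatives 2.58e-06 to 0.531, and adjusted p = 0.208 without B6 replicate 2, 0.0629 without B6 replicate 3, 0.499 without Tac146 replicate 2 and 0.245 without Tac146 replicate 3. Skeletal muscle genes were lower, with a median log2 fold change of -0.36 (camera, adjusted p = 2.38e-11), adjusted p = 0.222 with an estimated correlation, alternatives 1.98e-15 to 0.222. The muscle share was 4.37, 4.51 and 2.86% in Tac146 replicates 2, 3 and 4, and 4.66 to 5.55% in B6. Erythroid genes were lower, with a median log2 fold change of -0.73 (camera, adjusted p = 1.75e-05), adjusted p = 0.165 with an estimated correlation, alternatives 2.31e-08 to 0.165. Immediate early and stress genes were lower, with a median log2 fold change of -0.14 (camera, adjusted p = 0.000864), adjusted p = 0.165 with an estimated correlation, alternatives 0.000117 to 0.165. Fibroblast and matrix genes were lower, with a median log2 fold change of -0.21 (camera, adjusted p = 0.000126), adjusted p = 0.531 with an estimated correlation, alternatives 4.52e-09 to 0.531, and adjusted p = 0.157 without B6 replicate 2 and 0.372 without Tac146 replicate 4. Endothelial genes were lower, with a median log2 fold change of -0.14 (camera, adjusted p = 0.0108), adjusted p = 0.531 with an estimated correlation, alternatives 0.000410 to 0.766, and adjusted p = 0.766 without B6 replicate 2 and 0.112 without Tac146 replicate 4. Adipocyte genes were lower, with a median log2 fold change of -0.28 (camera, adjusted p = 0.00479), adjusted p = 0.531 with an estimated correlation, alternatives 6.45e-06 to 0.962, and adjusted p = 0.109 without B6 replicate 1, 0.0591 without B6 replicate 2 and 0.353 without Tac146 replicate 4. Mast cell markers were lower, with a median log2 fold change of -0.27 (camera, adjusted p = 0.00752), adjusted p = 0.531 with an estimated correlation, alternatives 9.27e-05 to 0.962, and adjusted p = 0.105 without B6 replicate 2 and 0.932 without Tac146 replicate 4. EdgeR called 0 members of the last 9 of these lists over all genes. Adjusted over the list alone, 2 neutrophil markers rose, and 2 skeletal muscle, 5 erythroid and 1 immediate early genes fell. At an unadjusted p under 0.05 there were 2 neutrophil, 1 MHC class II, 8 skeletal muscle, 5 erythroid, 4 immediate early, 3 fibroblast, 0 endothelial, 0 adipocyte and 0 mast cell genes, and DESeq2 called 1 neutrophil, 2 skeletal muscle and 1 immediate early genes and 0 of the others.

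Camera did not call the other lists between Tac146 and B6. By camera, median log2 fold changes were -0.25 (adjusted p = 0.610) for B and plasma cell markers, -0.01 (adjusted p = 0.692) for ILC2 and ILC3 markers, 0.02 (adjusted p = 0.808) for gamma chain genes and -0.10 (adjusted p = 0.142) for MHC class I genes. They were -0.01 (adjusted p = 0.953) for macrophage and dendritic cell markers, 0.03 (adjusted p = 0.774) for basal keratinocyte genes, 0.06 (adjusted p = 0.774) for melanocyte and Schwann cell genes and -0.01 (adjusted p = 0.975) for mitochondrial transcripts by camera. Proliferation genes had 0.29 (adjusted p = 0.0770), and camera adjusted p = 0.000549 without Tac146 replicate 3, alternatives 0.000549 to 0.608. Hair follicle genes had 0.16 (adjusted p = 0.229), with a camera test in the lower direction, and adjusted p = 0.0189 without B6 replicate 3, 0.000549 without Tac146 replicate 3 and 6.98e-12 without Tac146 replicate 4, alternatives 2.00e-12 to 0.842, the value without Tac146 replicate 3 being higher in direction. Macrophage and dendritic cell markers had camera adjusted p = 0.000240 without Tac146 replicate 4, alternatives 0.000137 to 0.992, in the opposite direction to the value with all libraries.

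EdgeR called 50 genes between Tac146 and B6, 32 higher and 18 lower in Tac146, of which 26 were over 2-fold higher and 17 over 2-fold lower. In 12.7% of the genes tested the libraries of the strains did not overlap, against 10% by chance. The count was 33 without B6 replicate 2 and 33 without B6 replicate 3. The split turned to 28 higher and 36 lower without B6 replicate 1, and was 22 higher and 11 lower without B6 replicate 2, 20 higher and 13 lower without B6 replicate 3 and 66 higher and 65 lower with DESeq2. The count was 131 with DESeq2, 129 with no filter on low counts and 26 with only the 6 libraries of these strains. In simulated counts for this comparison with 200 changed genes, edgeR recovered 23.9% of 1.5-fold, 77.6% of 2-fold and 90.9% of 4-fold changes, with 7 false calls. DESeq2 made 33 false calls in the same counts.

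The direct comparison of the Tac strains, whose libraries share the label T cells, asked which genes differed between them. Chil4, Sprr2a2 and Alox15 were far lower in Tac111 than in Tac146. Chil4 fell from 6950.3 ± 3062 to 0.675 ± 0.494 CPM (log2 fold change -13.35, SE 0.64, edgeR adjusted p = 1.94e-06). Sprr2a2 fell from 7775 ± 3145 to 5.61 ± 0.690 CPM (log2 fold change -10.44, SE 0.40, edgeR adjusted p = 5.62e-07) and Alox15 from 409 ± 109 to 4.02 ± 0.737 CPM (log2 fold change -6.67, SE 0.39, edgeR adjusted p = 8.49e-06). S100a9, a calcium-binding protein gene of neutrophils and stressed epithelium, was 32.3-fold lower (log2 fold change -5.01, SE 0.83, edgeR adjusted p = 0.00701). Of 35 differentiated keratinocyte genes, 4 fell and Krt2 rose (5 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.14 (camera, adjusted p = 7.27e-08), adjusted p = 0.164 with an estimated correlation, alternatives 1.40e-12 to 0.164. Krt2, a keratin gene of cornifying epithelium, stood at 950.2 ± 165 CPM in Tac111 and 209 ± 79.7 in Tac146 (log2 fold change 2.18, SE 0.36, edgeR adjusted p = 0.00642). Of 15 antimicrobial and interleukin 17 response genes, 5 fell (6 adjusted over the list alone), with a median log2 fold change of -0.79 (camera, adjusted p = 1.07e-06), adjusted p = 0.0698 with an estimated correlation, alternatives 9.56e-10 to 0.0698. Saa1 was 35.1-fold lower and Nfkbiz 2.71-fold lower (edgeR adjusted p = 0.000409 and 0.000183). Of 10 neutrophil markers, 4 fell (4 adjusted over the list alone), with a median log2 fold change of -0.83 (camera, adjusted p = 0.000755), adjusted p = 0.0557 with an estimated correlation, alternatives 8.23e-05 to 0.0557. Of 19 wound keratinocyte genes, 4 fell (4 adjusted over the list alone), with a median log2 fold change of -0.33 (camera, adjusted p = 0.00382), adjusted p = 0.149 with an estimated correlation, alternatives 9.53e-05 to 0.149. Genes higher in Tac111 included Aqp5 (log2 fold change 3.73, SE 0.35, edgeR adjusted p = 0.000216) and Atp5e (log2 fold change 3.09, SE 0.17, edgeR adjusted p = 4.47e-06). Wdfy1 (log2 fold change 2.27, SE 0.09, edgeR adjusted p = 5.62e-07) and Nnt (log2 fold change 1.89, SE 0.13, edgeR adjusted p = 2.92e-05) were also higher.

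Lymphocyte, interferon response and antigen presentation genes were also lower in Tac111 than in Tac146. Of 21 ILC1 and NK cell markers, 16 fell (19 adjusted over the list alone), with a median log2 fold change of -3.38 (camera, adjusted p = 1.29e-42), or -3.30 with genes at 0 set to their bound. This list and the MHC class I list passed with an estimated correlation (camera, adjusted p = 0.00648 and 0.0499). Itgae fell from 4.63 ± 0.699 to 0.210 ± 0.143 CPM (log2 fold change -4.41, SE 0.35, edgeR adjusted p = 8.31e-05), and Gzmc was at least 239-fold lower (edgeR adjusted p = 2.98e-05). Of 22 T cell markers, 9 fell (10 adjusted over the list alone), with a median log2 fold change of -0.92 (camera, adjusted p = 0.000143), adjusted p = 0.0510 with an estimated correlation, alternatives 1.79e-06 to 0.0510, and a median of -0.17 with genes at 0 set to their bound. Of 4 gamma delta T cell markers, Cd163l1 fell (1 adjusted over the list alone), with a median log2 fold change of -2.54 (camera, adjusted p = 0.0315), adjusted p = 0.149 with an estimated correlation, alternatives 0.00241 to 0.149, and a median of -0.90 with genes at 0 set to their bound. Of 32 interferon gamma response genes, 19 fell (26 adjusted over the list alone), with a median log2 fold change of -0.99 (camera, adjusted p = 1.92e-20), adjusted p = 0.113 with an estimated correlation, alternatives 6.60e-28 to 0.113. Of 43 type I interferon response genes, 6 fell (18 adjusted over the list alone), with a median log2 fold change of -0.69 (camera, adjusted p = 1.85e-08), adjusted p = 0.346 with an estimated correlation, alternatives 2.79e-14 to 0.346. Of 14 MHC class I genes, 8 fell (10 adjusted over the list alone), with a median log2 fold change of -0.50 (camera, adjusted p = 2.08e-18). Of 12 MHC class II genes, 9 fell (11 adjusted over the list alone), with a median log2 fold change of -1.24 (camera, adjusted p = 2.79e-15), adjusted p = 0.0510 with an estimated correlation, alternatives 1.00e-25 to 0.0510. Nlrc5 was 4.61-fold lower (log2 fold change -2.20, SE 0.17, edgeR adjusted p = 7.24e-05), and Ciita, the transactivator of MHC class II genes, was 3.21-fold lower (log2 fold change -1.68, SE 0.20, edgeR adjusted p = 0.000910).

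Further lists were called between Tac111 and Tac146. Of 16 gamma chain genes, 4 fell (5 adjusted over the list alone), with a median log2 fold change of -0.35 (camera, adjusted p = 7.34e-06), adjusted p = 0.0698 with an estimated correlation, alternatives 2.37e-07 to 0.0698. Of 12 ILC2 and ILC3 markers, 3 fell (3 adjusted over the list alone), with a median log2 fold change of -0.01 (camera, adjusted p = 0.0315), adjusted p = 0.149 with an estimated correlation, alternatives 0.000120 to 0.149, and adjusted p = 0.0670 without Tac146 replicate 3. Of 22 macrophage and dendritic cell markers, 5 fell (6 adjusted over the list alone), with a median log2 fold change of -0.36 (camera, adjusted p = 1.50e-05), adjusted p = 0.308 with an estimated correlation, alternatives 1.73e-14 to 0.308. Of 18 endothelial genes, 6 fell (8 adjusted over the list alone), with a median log2 fold change of -0.38 (camera, adjusted p = 1.90e-06), adjusted p = 0.205 with an estimated correlation, alternatives 3.48e-09 to 0.205. Of 17 basal keratinocyte genes, 3 fell (4 adjusted over the list alone), with a median log2 fold change of -0.24 (camera, adjusted p = 0.0315), adjusted p = 0.344 with an estimated correlation, alternatives 0.00444 to 0.344, and adjusted p = 0.0512 without Tac111 replicate 2 and 0.0738 without Tac146 replicate 4. Of 23 immediate early and stress genes, 3 fell (3 adjusted over the list alone), with a median log2 fold change of -0.20 (camera, adjusted p = 0.0348), adjusted p = 0.301 with an estimated correlation, alternatives 0.00559 to 0.301, and adjusted p = 0.100 without Tac111 replicate 1 and 0.0817 without Tac146 replicate 2. Higher in Tac111 were skeletal muscle genes (3 of 26 called, 4 adjusted over the list alone), with a median log2 fold change of 0.35 (camera, adjusted p = 0.000143), adjusted p = 0.377 with an estimated correlation, alternatives 8.07e-07 to 0.377. The muscle share was 4.885 to 5.245% in Tac111 and 2.86 to 4.51% in Tac146, where replicate 4 held the lowest value. Hair follicle and sebaceous gland genes were higher (3 of 26 called, 3 adjusted over the list alone), with a median log2 fold change of 0.64 (camera, adjusted p = 1.90e-06), adjusted p = 0.346 with an estimated correlation, alternatives 1.13e-27 to 0.346. Mast cell markers were higher, with a median log2 fold change of 0.48 (camera, adjusted p = 0.0202), adjusted p = 0.465 with an estimated correlation, alternatives 0.00146 to 0.465, and adjusted p = 0.0601 without Tac111 replicate 1 and 0.194 without Tac146 replicate 4. EdgeR called 0 of 9 mast cell markers (0 adjusted over the list alone), with 1 at an unadjusted p under 0.05 and 0 by DESeq2.

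Camera did not call the other lists between Tac111 and Tac146. By camera, median log2 fold changes were 0.14 (adjusted p = 0.108) for fibroblast and matrix genes, 0.06 (adjusted p = 0.112) for salivary and mucous gland genes with a camera direction of lower, and -0.37 (adjusted p = 0.497) for adipocyte genes. They were -0.06 (adjusted p = 0.553) for melanocyte and Schwann cell genes, 0.29 (adjusted p = 0.131) for erythroid genes, 0.09 (adjusted p = 0.497) for proliferation genes and 0.19 (adjusted p = 0.119) for mitochondrial transcripts by camera. Within these lists edgeR still called 1 higher and 4 lower of 9 salivary and mucous gland (1 higher and 4 lower adjusted over the list alone), 2 lower of 7 B and plasma cell (3 lower adjusted over the list alone), 1 higher of 23 fibroblast (0 adjusted over the list alone), 1 lower of 15 adipocyte (1 lower adjusted over the list alone) and 1 lower of 15 melanocyte and Schwann cell (1 higher and 2 lower adjusted over the list alone) genes. B and plasma cell markers had -0.55 (adjusted p = 0.0659), and camera adjusted p = 0.0313 without Tac111 replicate 3 and 0.0189 without Tac146 replicate 4, alternatives 0.0189 to 0.309. Fibroblast genes had camera adjusted p = 0.0221 without Tac111 replicate 3 and 0.00182 without Tac146 replicate 2, alternatives 0.00182 to 0.907. Adipocyte genes had camera adjusted p = 0.0226 without Tac146 replicate 4, alternatives 0.00408 to 0.995. Erythroid genes had camera adjusted p = 0.0157 without Tac111 replicate 2 and 0.0267 without Tac146 replicate 3, alternatives 0.0157 to 0.489. Mitochondrial transcripts had camera adjusted p = 0.0480 without Tac111 replicate 2, alternatives 0.0480 to 0.489.

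**Figure D4:**
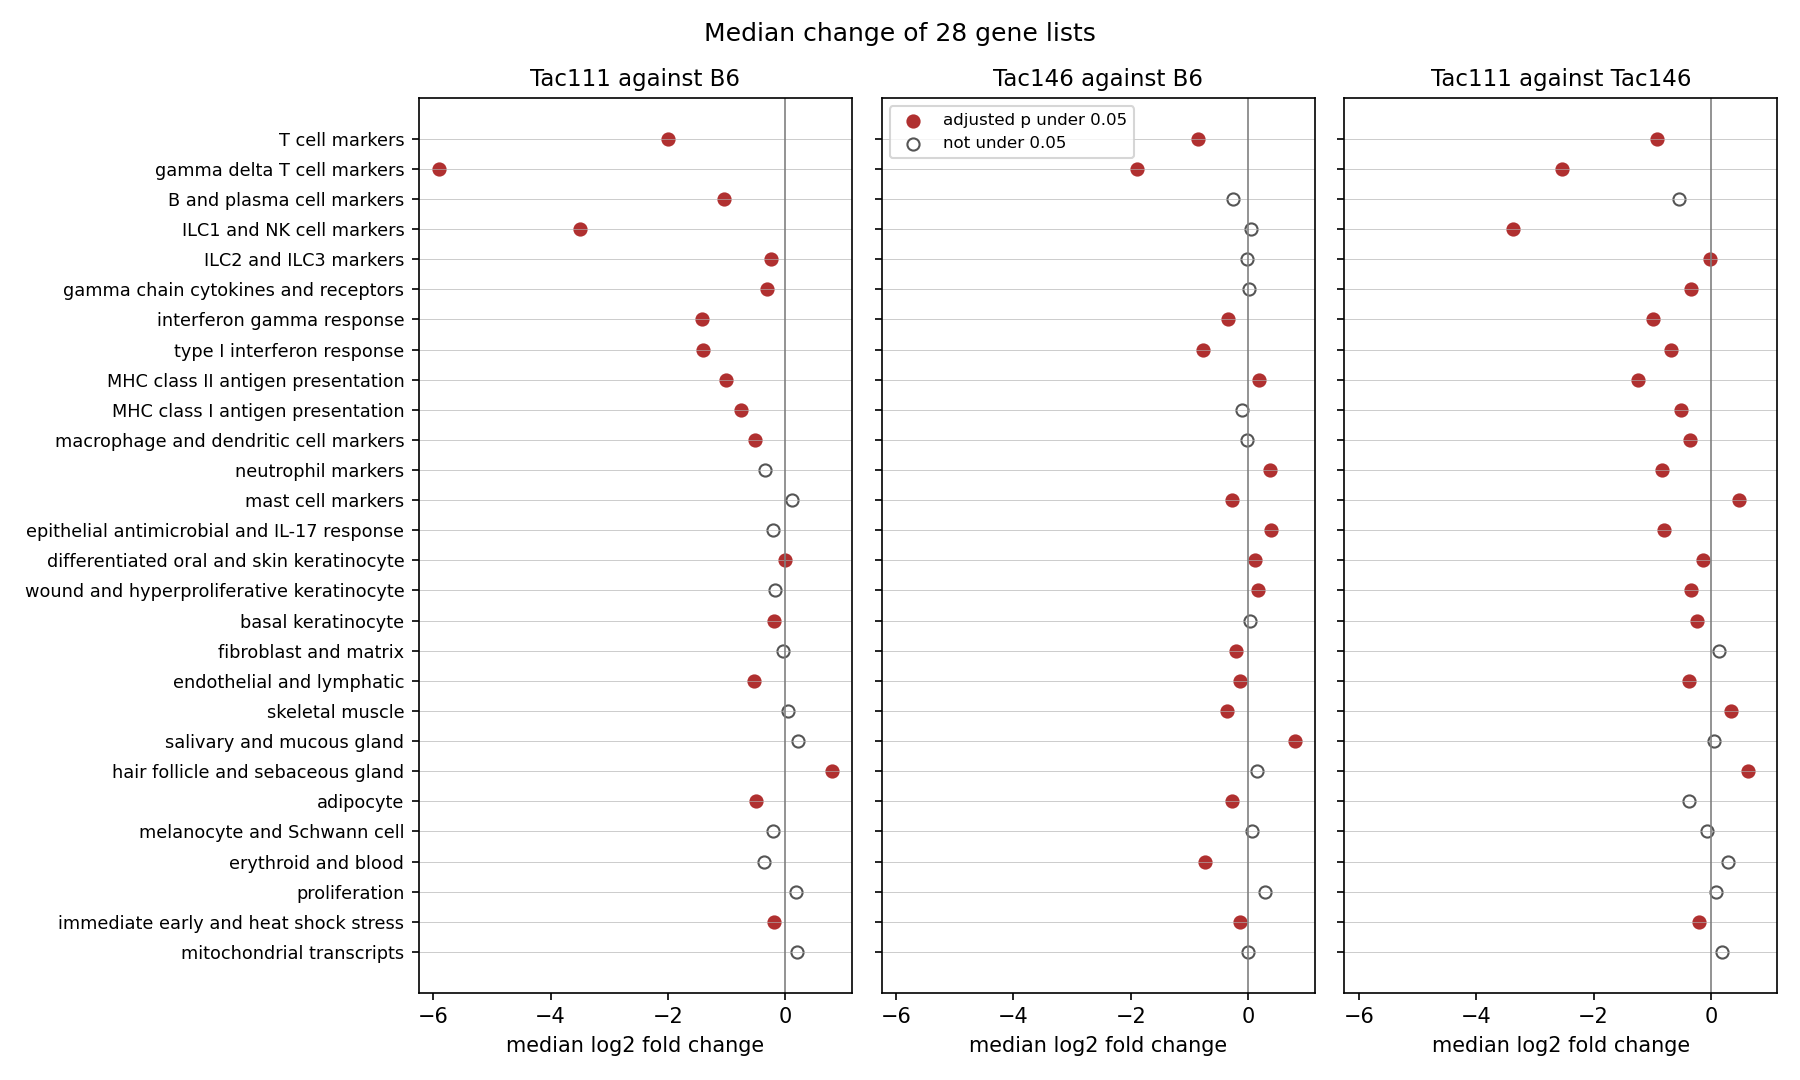
Median log2 fold change (x axis) of each of 28 gene lists (y axis) in the 3 comparisons, filled where camera gave an adjusted p under 0.05 with a preset correlation of 0.01. The ILC1 and NK cell markers lay at -3.49 in Tac111 against B6, 0.05 in Tac146 against B6 and -3.38 in Tac111 against Tac146.

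EdgeR called 1469 genes between Tac111 and Tac146, 433 higher and 1036 lower in Tac111, of which 79 were over 2-fold higher and 314 over 2-fold lower. With upper-quartile factors the split was 609 higher and 822 lower, so the share of lower calls went from 70.5% to 57.4%. In 35.5% of the genes tested the libraries of the strains did not overlap, against 10% by chance. The count was 793 without B6 replicate 2, 907 without Tac111 replicate 1, 483 without Tac111 replicate 2, 470 without Tac111 replicate 3, 498 without Tac146 replicate 3 and 878 without Tac146 replicate 4. Higher calls were 273, 173 and 241 without B6 replicates 1, 2 and 3 and 238, 115 and 91 without Tac111 replicates 1, 2 and 3. They were 554, 121 and 259 without Tac146 replicates 2, 3 and 4. The count was 2572 with DESeq2, 641 with only the 6 libraries of these strains and 632 with a replicate block. In simulated counts for this comparison with 200 changed genes, edgeR recovered 28.4% of 1.5-fold, 71.6% of 2-fold and 95.5% of 4-fold changes, with 8 false calls. DESeq2 made 33 false calls in the same counts.

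Across all 3 strains, edgeR called 806 genes, with 4262 at an unadjusted p under 0.05. That count was 457 without B6 replicate 2, 410 without Tac111 replicate 1, 315 without Tac111 replicate 2, 344 without Tac111 replicate 3 and 528 without Tac146 replicate 3. Against B6, 13 genes were called in the same direction in both Tac strains. The 11 lower genes included Cd3d, Cd3e, Cd3g, Trac, Trdc, Cd59a, Cd59b and Ifi27l2a, and the 2 higher genes were Mgst2 and Gm7658, named after their values were seen. Mgst2 lay close to the threshold in Tac146 (edgeR adjusted p = 0.0411, and 0.0199 in Tac111). Another 11 genes were lower in Tac111 and higher in Tac146. Independent lists of these sizes would share 0.503 lower and 0.325 higher genes and 0.895 genes of opposite direction, values that leave out the shared B6 libraries. In 20 simulations of unchanged strains, with simulated B6 libraries common to both comparisons, 0 were shared, which is chance with no effect and is no reference for lists of these sizes. The 3 B6 libraries cannot be split into sets of 2, so part of the excess over independent lists may come from the shared controls. The number in the same direction was 29 without B6 replicate 1, 5 without B6 replicate 2, 6 without B6 replicate 3, 7 without Tac146 replicate 3 and 8 without Tac146 replicate 4. Across genes, which are not independent replicates, the fold changes against B6 correlated with r = 0.209, against 0.511 in the simulations. Their covariance was 0.0458, against 0.0314 in the simulations, a difference of 0.0144.

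The position of called genes around Rag1 with Rag2 and around Il2rg was compared with all other tested genes. Within 10 Mb of Rag1, 8 of 85 tested genes were called between Tac111 and B6, an odds ratio of 2.66 (95% interval 1.10 to 5.54). Between Tac146 and B6, 2 of 85 were called, Cd59a and Cd59b, an odds ratio of 8.56 (95% interval 0.990 to 33.7). Both had an adjusted p of 0.0764 by two-sided Fisher's exact test, adjusted over 6 tests. In windows of 5 Mb the adjusted exact p was 0.0148 and 0.0156, and over both other windows it ranged up to 0.668. Between Tac111 and Tac146 the adjusted exact p within 10 Mb of Rag1 was 1. Within 10 Mb of Il2rg the adjusted exact p was 1 in all 3 comparisons.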

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

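The tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the libraries.

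For 11 genes and the MHC class II list, the effects of the Tac strains against B6 went in opposite directions, both called, and the difference between the Tac strains was itself called by edgeR or camera. That difference follows from opposite effects against the same B6 libraries, so its call is no separate evidence. The log2 fold changes of Tac111 against Tac146 were -11.08 for Sprr2a3, -10.44 for Sprr2a2, -8.16 for Sprr2a1, -6.99 for Sprr2f and -3.53 for Sprr2j-ps. They were -5.17 for Chil1, -4.51 for Gsdmc2, -2.21 for Crispld2, -1.44 for Nfkbiz, -1.80 for Tmem254b and -1.83 for Tmem254c, of which the last pair can share reads. For Sprr2a2 the changes against B6 were -8.32 and 2.12 in Tac111 and Tac146. For Chil1 they were -1.77 and 3.40, and for Crispld2 -0.73 and 1.48. Some calls against B6 were lost when single libraries were left out. For Sprr2a3 in Tac146, edgeR gave adjusted p = 0.0510 without B6 replicate 1, 0.128 without B6 replicate 2 and 0.0594 without B6 replicate 3 (alternatives 6.04e-06 to 0.128). For Sprr2f in Tac111, edgeR gave adjusted p = 0.0927 without B6 replicate 1, 0.0850 without B6 replicate 3, 0.0848 without Tac111 replicate 1, 0.0625 without Tac111 replicate 2 and 0.134 without Tac111 replicate 3 (alternatives 0.000376 to 0.134). For Sprr2j-ps in Tac111, edgeR gave adjusted p = 0.0566 without B6 replicate 1, 0.0629 without B6 replicate 3, 0.0609 without Tac111 replicate 1 and 0.0779 without Tac111 replicate 3 (alternatives 2.01e-05 to 0.0779). For Chil1 in Tac111, edgeR gave adjusted p = 0.118 without B6 replicate 1, 0.114 without B6 replicate 3, 0.115 without Tac111 replicate 1, 0.0670 without Tac111 replicate 2, 0.169 without Tac111 replicate 3 and 0.0630 without Tac146 replicate 3 (alternatives 0.000688 to 0.169). For Gsdmc2 in Tac146, edgeR gave adjusted p = 0.133 without B6 replicate 1, 0.246 without B6 replicate 2, 0.0720 without B6 replicate 3, 0.0840 without Tac111 replicate 1, 0.0871 without Tac111 replicate 2, 0.0945 without Tac111 replicate 3 and 0.0521 without Tac146 replicate 3 (alternatives 5.27e-06 to 0.246). For Nfkbiz in Tac111, edgeR gave adjusted p = 0.0603 without B6 replicate 1, 0.0822 without Tac111 replicate 2 and 0.0660 without Tac111 replicate 3 (alternatives 0.000392 to 0.0822). For Nfkbiz in Tac146, edgeR gave adjusted p = 0.243 without B6 replicate 2, 0.173 without B6 replicate 3, 0.0666 without Tac111 replicate 1, 0.0769 without Tac111 replicate 2, 0.0767 without Tac111 replicate 3, 0.181 without Tac146 replicate 3 and 0.0963 without Tac146 replicate 4 (alternatives 7.63e-05 to 0.243). For Tmem254b in Tac146, edgeR gave adjusted p = 0.0596 without B6 replicate 1, 0.0658 without Tac111 replicate 2, 0.0533 without Tac146 replicate 2, 0.0874 without Tac146 replicate 3 and 0.0617 without Tac146 replicate 4 (alternatives 2.57e-06 to 0.115). The MHC class II list had a median of -1.24 in Tac111 against Tac146. Its call in Tac146 against B6 was lost without some libraries, with camera adjusted p = 0.208 without B6 replicate 2, 0.0629 without B6 replicate 3, 0.499 without Tac146 replicate 2 and 0.245 without Tac146 replicate 3. With an estimated correlation camera gave adjusted p = 0.531 there (alternatives 2.58e-06 to 0.531) and 0.0510 in Tac111 against Tac146 (alternatives 1.00e-25 to 0.0510). The differentiated keratinocyte list was called lower in Tac111 and higher in Tac146 by camera, but its medians against B6 were 0.00 and 0.12, and against B6 edgeR called only Sprr2a1, Sprr2a2 and Sprr2a3 of its members. Its median in Tac111 against Tac146 was -0.14. With an estimated correlation camera gave it adjusted p = 0.245, 0.299 and 0.164 for Tac111 against B6, Tac146 against B6 and Tac111 against Tac146 (alternatives 7.52e-09 to 0.245, 2.43e-07 to 0.299 and 1.40e-12 to 0.164).

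Of the Sprr2 genes, 5 were called lower in Tac111 and higher in Tac146 against B6, while Sprr2k was called in no comparison (edgeR adjusted p = 0.324, 0.928 and 0.397). Reads shared among near-identical Sprr2 copies would leave their sum alike across strains, but the sum of 13 Sprr2 genes was 1965 ± 490.5 CPM in B6, 43.8 ± 7.59 in Tac111 and 8474 ± 3369 in Tac146 (SD, n = 3), 4.31-fold higher in Tac146 than in B6. Sprr2a2 alone made up 1793, 5.61 and 7775 CPM of these sums. A different share of differentiated epithelium would move its other genes alike. The differentiated keratinocyte list, which includes Sprr2a1, Sprr2a2 and Sprr2a3, moved little between Tac146 and B6 (median log2 fold change 0.12, quartiles 0.05 and 0.27). The 11 genes had quartiles of 1.24 and 2.18. They were picked for being called higher in Tac146, so the gap to the list was set by that choice and is no test of this share. More Il13 transcripts in Tac146 may be a source of the difference: the libraries held 5, 11 and 20 Il13 counts in Tac146, 3, 3 and 1 in B6 and 0 in Tac111. Il13 was not alone in this order. Summed over the libraries of B6, Tac111 and Tac146, Il22 had 1.99, 0 and 14 expected counts and Ifng 4, 0 and 7. Il4 (9, 4 and 3), Il5 (26, 39 and 31) and Il17a (2, 0 and 1) did not follow it. The exact two-sided permutation p of Il13 in Tac146 against B6 was 0.1, the smallest that 3 against 3 can give, so a role of Il13 stays open. Both Tac strains share the label T cells, so the labelled cell type cannot account for the difference between Tac111 and Tac146. Against B6, strain and labelled cell type changed together, and neither was tested apart. T cell markers were nonetheless lower in both Tac strains, labelled T cells, than in B6, labelled ILC1. Their median log2 fold changes were -2.00 in Tac111 and -0.86 in Tac146. These values argue against RNA of the labelled cells as the source of the differences from B6.

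The libraries are labelled as T cells or ILC1 cells but held abundant keratin and muscle transcripts. RNA of the labelled cells alone was argued against by Krt13 counts of at least 2441 times the Ptprc counts in every library. RNA of whole mucosal biopsies may account for this: the medians of 6 of 6 lists (2 keratinocyte lists, fibroblast, endothelial, muscle and mast cell) lay above the T cell list in all 9 libraries, and 0 genes of these 6 lists stood in another list. The T cell list had a median CPM of only 0.108 to 1.00, so most expressed lists would lie above it and this result could hardly fail. The ILC1 and NK cell list was not used as the reference for the B6 libraries. Krt4 and Krt13, the abundant keratinocyte genes, took 5.28 to 8.87% of the counts. A sort for lymphocytes would remove such cells, and the labels describe no sort.

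In the test across the 3 strains, 2 of 100 splits of the 9 libraries into groups of 3 called as many genes as the real one (806), the real one included. Most drawn splits broke up the Tac111 libraries, which puts the Tac111 difference within groups, so this share does not exclude chance for the grouping into 3 strains. The highest other split called 1643 genes. It kept the Tac111 libraries together and set B6 replicate 3 with Tac146 replicates 3 and 4, and B6 replicates 1 and 2 with Tac146 replicate 2. The other 2 drawn splits that kept the Tac111 libraries together called 358 and 305 genes. The splits therefore tell Tac111 from the other libraries, but do not exclude chance for the parting of B6 from Tac146. In the pair test of Tac146 against B6, each of these splits called 0 genes between its mixed groups. Their calls across 3 groups therefore set Tac111 apart and are no rival parting of B6 and Tac146. Why the highest one called more than the real one was not tested. Between pairs of strains, 1 of 10 splits, the real one, called as many genes in each comparison, and 10 splits are too few for a share under 0.05. The real counts were 630, 50 and 1469 for Tac111 against B6, Tac146 against B6 and Tac111 against Tac146, and the highest other splits called 1, 0 and 0. Each other split mixes the strains of the pair, which puts their difference within groups. Its low count was thus largely set in advance and is no support for the real one.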

How the results depend on the processing

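Limma on log2(CPM + 1) and robust dispersions were tests chosen after the results were seen, and the genes the rule does not take were added then. Limma on log2(TPM + 1), planned, was not run because the files used give no TPM or gene length. Of 452 results for named genes, 232 were called, 156 of them under every alternative, and 76 lost the call under at least 1. Of 220 not called, 66 passed under at least 1, and 0 called values changed direction. Il2rg kept its call, with -5.44 to -5.33 when single libraries were left out, and the calls of Rag1 in Tac146 against B6 and of Rag2 in Tac111 against B6 were kept as well.

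DESeq2 called 1161 genes for Tac111 against B6, 131 for Tac146 against B6, 2572 for Tac111 against Tac146, 2062 across the 3 strains and 41 in the same direction against B6. It was run without the expression filter of edgeR and gave adjusted p-values for 17921, 18455 and 16854 genes in these comparisons of strain pairs. No filter on low counts gave 1020, 129, 1695 across strains and 41 in the same direction, with more genes tested. The filter of 1 CPM in 3 libraries gave 6 in the same direction. With only the 6 libraries compared, 882 genes were called for Tac111 against B6 (311 higher and 571 lower), 26 for Tac146 against B6 and 641 for Tac111 against Tac146. Leaving out single libraries gave 295 to 958 genes for Tac111 against B6, 33 to 64 for Tac146 against B6, 470 to 1829 for Tac111 against Tac146, 315 to 1066 across strains and 5 to 29 in the same direction. Lists called ranged from 16 to 22, 12 to 18 and 18 to 22 in the same order of comparisons. An estimated correlation left 8, 2 and 2 lists, and fry 4 for Tac146 against B6. Reversed for Tac146 against B6 were the hair follicle list without Tac146 replicate 3 (camera adjusted p = 0.000549, left-out range 6.98e-12 to 0.804), the macrophage list without Tac146 replicate 4 (0.000240, left-out range 0.000240 to 0.992) and with the replicate block (0.000137), and the mast cell list with the block (0.962). The cause of these changes was not tested.

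Within 10 Mb of Rag1, the odds ratio of a call was 2.66 for Tac111 against B6 and 8.56 for Tac146 against B6 (Fisher's exact test, adjusted p = 0.0764 for both). Within 5 Mb it was 4.95 (adjusted p = 0.0148, range 0.0148 to 0.668) and 20.3 (adjusted p = 0.0156, range 0.0156 to 0.668). The replicate block gave 874 genes for Tac111 against B6, 44 for Tac146 against B6, 632 for Tac111 against Tac146 and 7 in the same direction. Deviations of same-numbered libraries correlated at -0.0893 to 0.206, and not every library correlated best with its own number. With so few libraries this gives no sign of pairing but cannot exclude it, and the labels do not say what the numbers mean.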

Other observations

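The genes, the families and the reading of the position test below were chosen after the results were seen, while the position test itself was set before.

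Snhg1, Ccnl2, Cirbp and Neat1 were higher in Tac111 than in B6. Snhg1 is a host gene of small nucleolar RNAs (log2 fold change 0.59, SE 0.09, edgeR adjusted p = 0.00437), Ccnl2 a cyclin of splicing (log2 fold change 0.69, SE 0.08, edgeR adjusted p = 0.000798), Cirbp a cold-inducible RNA-binding protein gene (log2 fold change 0.54, SE 0.08, edgeR adjusted p = 0.00437) and Neat1 a nuclear RNA (log2 fold change 0.74, SE 0.12, edgeR adjusted p = 0.00835). Of 14 tested Snhg genes, 6 were called higher and 13 had a positive fold change, with a median log2 fold change of 0.59, or 0.59 with median-ratio and 0.62 with upper-quartile factors. Against Tac146, 5 were called higher, with a median of 0.41. Of these, Snhg1, Snhg3, Snhg5 and Snhg6 lay near the threshold (edgeR adjusted p = 0.0431, 0.0473, 0.0490 and 0.0340). The Snhg genes were picked for their rise, so no p-value is given for the family. The share of mitochondrial transcripts was also higher in Tac111 (6.08 to 7.50%) than in B6 (5.38 to 6.02%), and a link between these changes and RNA quality was not tested.

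Ccr7, a chemokine receptor gene, and the chemokine genes Ccl17 and Ccl22 were lower in Tac111 than in B6. Ccr7 had 58 counts in the B6 libraries and 1 in the Tac111 libraries, a ratio of 53.7 (95% counting interval 9.26 to 2155, edgeR adjusted p = 0.00141). Ccl17 (log2 fold change -3.33, SE 0.45, edgeR adjusted p = 0.00261) and Ccl22 (log2 fold change -2.22, SE 0.18, edgeR adjusted p = 0.000150) fell, and so did Ptprc (log2 fold change -1.26, SE 0.12, edgeR adjusted p = 0.000389). Against Tac146, with 54 Ccr7 counts, the ratio for Ccr7 was 40.9 (95% counting interval 7.04 to 1645, edgeR adjusted p = 0.00205). The changes of Ccl17 and Ccl22 were -2.96 and -2.05 (edgeR adjusted p = 0.00447 and 0.000177).

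Cd59a and its neighbour Cd59b, both on chromosome 2 with Rag1 and Rag2, were lower in both Tac strains than in B6. Called genes made up 9.41% of the 85 tested genes within 10 Mb of Rag1 for Tac111 against B6, and 3.76% of the others. For Tac146 against B6 the shares were 2.35%, Cd59a and Cd59b alone, and 0.281%. DNA around a targeted Rag1 or Rag2 allele from another mouse strain could be a source, but the labels give no genotype, the test includes the genes that prompted it, and the larger adjusted p of Fisher's exact test was 0.0764, so this stays open.

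Cd59b in Tac111 against B6 had edgeR adjusted p = 0.0155, and 0.0518 without B6 replicate 1, 0.0557 without B6 replicate 2, 0.0569 without B6 replicate 3, 0.0747 without Tac111 replicate 2 and 0.0773 without Tac111 replicate 3 (alternatives 0.00455 to 0.0773). In Tac146 against B6 it had edgeR adjusted p = 0.0171, and 0.0554 without B6 replicate 1, 0.0830 without B6 replicate 2, 0.0720 without B6 replicate 3 and 0.0893 without Tac146 replicate 3 (alternatives 0.00114 to 0.0909).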
